A study of Caenorhabditis elegans with 32 samples.

How the data were processed

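Transcript levels were measured by RNA sequencing of polyA-selected RNA from whole worms of 4 genotypes in 2 conditions, with strand-specific libraries on a HiSeq2500. The labels describe 32 samples in 8 groups, 4 replicates per group. The table analysed here has 30 library columns, all matched to a sample, and 2 samples (refed hlh-30 mutants replicate 4 and daf-1 mutants in ARD replicate 3) were not analysed here. Its unit is a signal: read counts per gene that the authors scaled between libraries, called normalized counts in the text. Per the submitters' processing notes, HISAT2 2.0.4, Cuffdiff 2.2.1, DESeq2 and the WBcel235 assembly were used, with no role stated for each. Low values of a library lie near multiples of a step of 0.73 to 1.44, but only 43 to 91% of the values up to 20 steps lay within 0.1 step of a multiple, so whole reads were not recovered and tests made for counts were not run. The table holds 18940 genes, the lowest with a mean of 1.82, and genes below that were not analysed here.

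Sums per library ran from 26238915 to 32238033 and medians over genes from 183 to 260. The step put the reads behind them at about 21900000 to 36000000, and the 10 most abundant genes took 6.3 to 13.6% of a library. Over abundant genes, the variance between a pair of libraries of a group was at least 7 times that of counting error in every pair; less abundant genes were not compared.

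Groups were taken from the sample titles. In 16 samples the treatment tag names the other condition: 8 samples with refeeding in the title have none in the tag, and 8 without it in the title have it in the tag, and the tag follows the genotype. The batch tag differs from the number in the title in 5 samples. Residual profiles of libraries with the same number had a mean correlation across genes of 0.08 (-0.38 to 0.74 over 98 pairs, 35 above 0.1) against -0.03 (-0.68 to 0.52 over 295 pairs) for different numbers, and 0.09 for the same batch tag. The model had no block, as fixed before the data were examined, and a block by title number or by batch tag was an alternative.

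Values were transformed to log2 after adding 1, and genes with at least 10 normalized counts in at least 4 libraries were tested (17996 of 18940, 95%). One linear model with 8 group means was fitted with limma 3.58.1 (trend) in R 4.3.3 for 16 comparisons, 12 of 2 groups and 4 interactions, and p-values were adjusted by the Benjamini-Hochberg method over genes within each comparison, with a threshold of 0.05, all two-sided. The design had placed a test for counts first and named this model for normalized values. Adding 1 shrinks the fold changes of genes with low values. Checked on simulated data made from these libraries with 200 changed genes, the model recovered 64 of 100 2-fold and 84 of 100 4-fold changes between hlh-30 mutants and N2 in ARD, with 11 false calls, and 60 and 90 of 100 after refeeding, with 3.

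Gene lists, comparisons, the model and the rule for named genes were chosen before the data were examined. The 34 lists were tested with camera (limma) with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. They cover metabolism (lipases, fatty acid synthesis and desaturation, fatty acid beta-oxidation, gluconeogenesis with the glyoxylate cycle and trehalose, oxidative phosphorylation, xenobiotic detoxification), autophagy, lysosomal hydrolases and membrane proteins, and V-ATPase. They also cover vitellogenins, germ cells and meiosis, oocyte and early embryo, sperm, DNA replication and cell cycle, DNA damage and apoptosis, ribosomal proteins, ribosome biogenesis and RNA polymerase I, and the cytosolic, ER and mitochondrial stress responses. The others are DAF-16 and insulin-signalling responsive genes, insulin-like peptides, the TGF-beta pathway, dafachronic acid synthesis and receptor, cuticle collagens, molting cycle, C-type lectins, antimicrobial and pathogen response, and markers of intestine, body wall muscle, pharynx, neurons, epidermis and somatic gonad. Of the genes in the table, 193 share their values with another gene in every library, 154 of them tested.

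Named genes are hlh-30 and daf-1 first. Then come the 8 largest rises and 8 largest falls (4 and 4 in the other comparisons and the interactions) among called genes with a mean of at least 50, a name of 3 or 4 letters and, in comparisons of 2 groups, no overlap between the values of the groups, so every library of one group lay above every library of the other. From each list up to 4 members with the smallest p could be named. The first 4 comparisons and refeeding of N2 and of hlh-30 mutants had 8 and 8. Errors are SD for normalized counts and SE for log2 changes. Positions and gene types come from Ensembl release 115, which held 18852 of the genes.

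Alternatives were quantile normalization, pseudocounts of 0.5 and 5, no filter, a fit of the compared groups alone, both blocks, and leaving out each library. Library weights and leaving out the 3 libraries farthest from their group mean were added after the data were seen. Summary tables and figures used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.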

Results

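RNA was sequenced from whole worms of 4 genotypes in 2 conditions. The genotypes were N2 (wild type), hlh-30(tm1978), daf-1(m40) and the hlh-30 daf-1 double mutant. The gene hlh-30 encodes the worm orthologue of the transcription factor TFEB, and daf-1 encodes a type I receptor of the TGF-beta pathway. In the ARD condition, worms moved at the mid-L3 larval stage to agarose plates without food were collected after 48 h in adult reproductive diapause (ARD), a starvation-induced arrest of reproduction. In the refed condition, worms were returned to food for 12 h after 48 h of ARD. Of the 32 samples described, 30 had a column of values: 4 libraries per group, and 3 each for refed hlh-30 mutants and daf-1 mutants in ARD. The other 2 samples were not analysed here. Groups follow the sample titles; in 16 of the 32 samples the treatment tag names the other condition. Values are the authors' normalized read counts per gene, whose sums ran from 26238915 to 32238033 per library. The spacing of low values put the reads behind them at about 21900000 to 36000000.

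The first 2 principal components held 30.1% and 20.5% of the variance. Libraries of the double mutant in ARD lay at -138 to -70 on the first component and those of refed N2 at 83 to 107. On the second component, refed daf-1 mutants lay at -110 to -83 and hlh-30 mutants in ARD at 48 to 56. The 3 libraries that stood apart from their groups had an SD over genes of the log2 deviation from the group mean of 0.63 for N2 in ARD replicate 2, 0.71 for the double mutant in ARD replicate 1 and 0.63 for the refed double mutant replicate 1. The lowest SD of any library was 0.22. Germline and yolk genes differed within groups as well as between them. The mean log2 level of the oocyte and early embryo list ran from 9.6 to 12 in the 4 N2 libraries in ARD and from 8.43 to 10.21 in those of the double mutant, against 13.04 to 13.34 in refed daf-1 mutants.

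**Figure D1:**
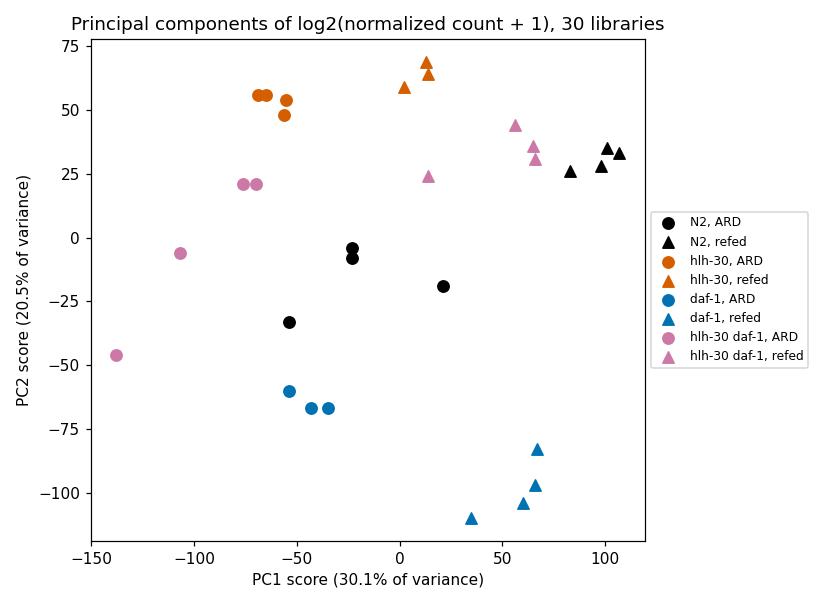
Scores of the 30 libraries on the first (30.1% of the variance) and second (20.5%) principal component of log2 normalized counts; colours give the genotype and marker shapes the condition. Refed N2 libraries lie at 83 to 107 on the first component.

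The deleted gene itself was followed first. On the WBcel235 assembly hlh-30 (WBGene00020930) lies on chromosome IV at 4014793 to 4034951. Its transcript level was 1302 normalized counts on average (1177 to 1469, n = 4) in N2 in ARD and 729 ± 177 (SD, n = 4) in hlh-30 mutants, a log2 change of -0.87 ± 0.17 (SE; adjusted p = 0.000151, limma). After refeeding it was 600 ± 45 (n = 4) in N2 and 421 ± 30 (n = 3) in hlh-30 mutants, a change of -0.51 ± 0.18 (adjusted p = 0.0297). That call was lost with quantile normalization (adjusted p = 0.0609), without N2 refed replicate 1 (0.0693) or 4 (0.0555), and without hlh-30 refed replicate 2 (0.0731) or 3 (0.0992). In daf-1 mutants hlh-30 stood at 1255 ± 250 (n = 3) in ARD and 608 ± 111 (n = 4) after refeeding, and in double mutants at 592 ± 64 and 294 ± 69 (n = 4 each). The daf-1 gene (WBGene00000897, chromosome IV, 132416 to 138081) was at 620 ± 38 in N2 and 615 ± 75 in daf-1 mutants in ARD, a log2 change of -0.02 ± 0.11 (adjusted p = 0.931). After refeeding it was at 535 ± 50 in N2 and 732 ± 68 in daf-1 mutants (log2 change 0.45 ± 0.10, adjusted p = 0.000262). In double mutants it was at 544 ± 57 in ARD and 419 ± 30 after refeeding (n = 4 each). The refed level differed by -0.35 ± 0.10 from N2 (adjusted p = 0.00664) and by -0.34 ± 0.11 from hlh-30 mutants (adjusted p = 0.0149). The first call was lost with quantile normalization (adjusted p = 0.0501), and the second without hlh-30 refed replicate 1 (0.0501) or 2 (0.0599) or double mutant refed replicate 3 (0.0503). The effect of losing daf-1 on its own level after refeeding differed between the backgrounds, by -0.79 ± 0.14 (adjusted p = 6.59e-05). A level per gene does not test whether either allele was present.

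**Figure D2:**
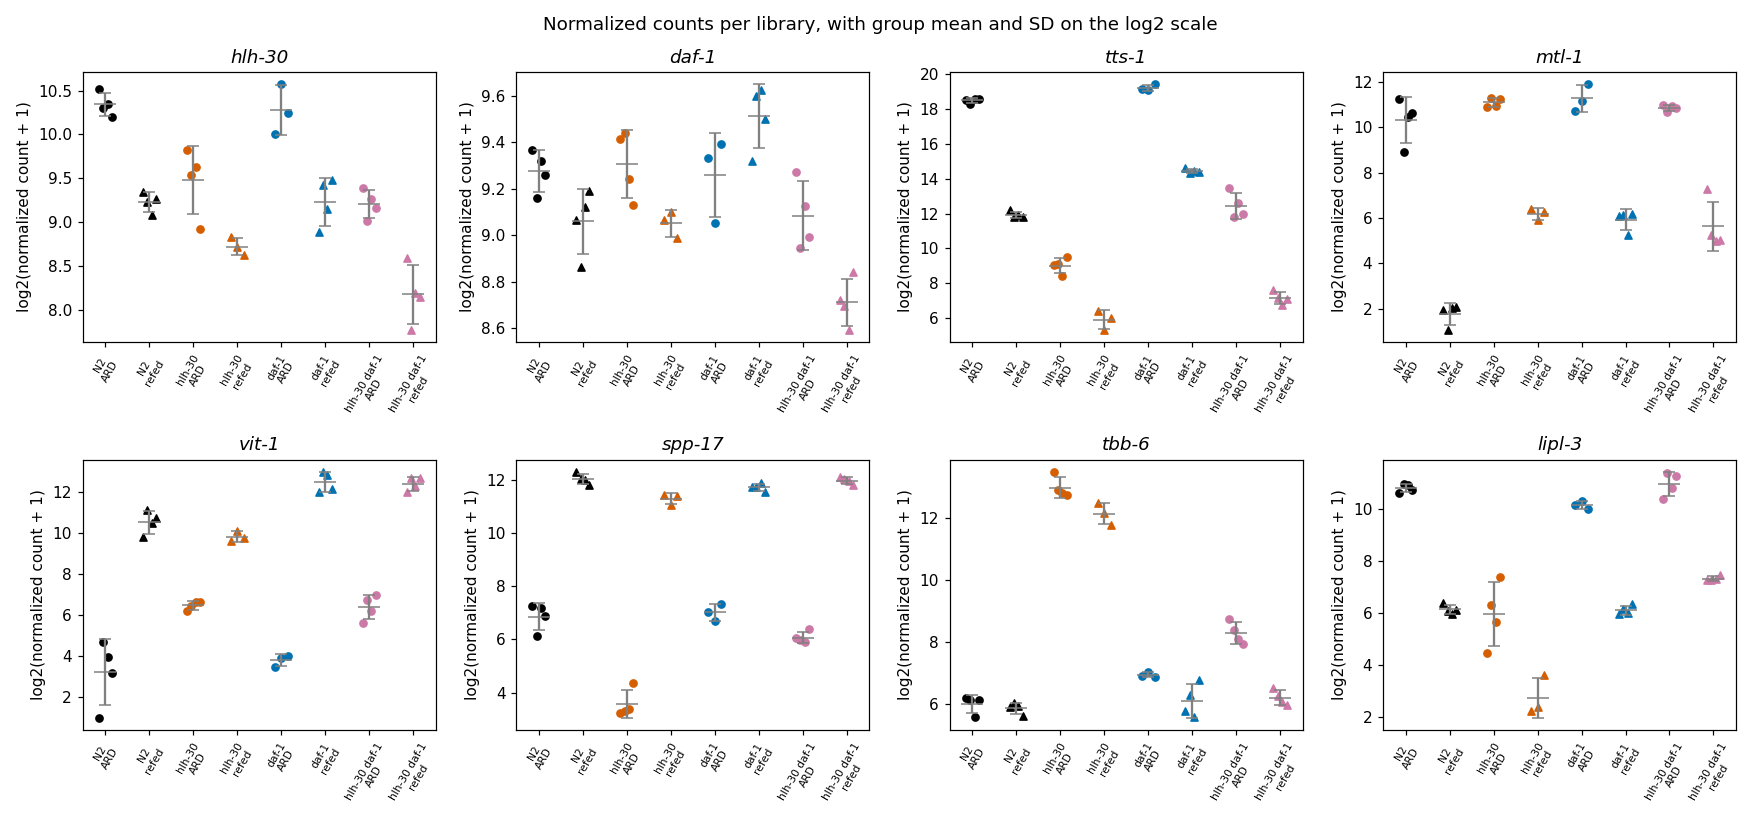
Normalized counts of 8 genes on a log2 scale, after adding 1, in each library of the 8 groups; points are libraries and the grey marks are the group mean and SD on that scale. The non-coding RNA tts-1 is at 373232 ± 35340 normalized counts (SD, n = 4) in N2 in ARD and 533 ± 156 (n = 4) in hlh-30 mutants.

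The comparison of hlh-30 mutants with N2 in ARD asked which transcripts depended on hlh-30 during the arrest. The long non-coding RNA tts-1 (WBGene00006650, chromosome X, 1504131 to 1504841), which is abundant in long-lived and arrested worms, fell the furthest of the genes named by the rule, from 373232 ± 35340 normalized counts in N2 to 533 ± 156 (SD, n = 4 each; log2 change -9.49 ± 0.27 SE, adjusted p = 1.52e-19). The F-box gene fbxa-24 fell by 7.63 ± 0.25 on the log2 scale and the aldehyde dehydrogenase gene alh-5 by 5.52 ± 0.16. The cathepsin B-like protease gene cpr-2, the cuticle collagen gene col-88, the chitinase-like gene chil-28 (annotated as a pseudogene) and the cytochrome P450 genes cyp-34A9 and cyp-34A10 also fell, with log2 changes from -7.46 to -5.32. Among the genes that rose, parg-2, which encodes a poly(ADP-ribose) glycohydrolase, went from 110 ± 19 to 18067 ± 398 (log2 change 7.36 ± 0.47, adjusted p = 8.42e-13). The beta-tubulin gene tbb-6 rose from 63.8 ± 11.4 to 8281 ± 2186 (6.98 ± 0.23, adjusted p = 2.36e-18). The Rab GTPase gene rab-11.2 rose by 7.42 ± 0.45, the cyclic nucleotide-gated channel gene cng-1 by 6.82 ± 0.37, and irg-5, an infection response gene, by 7.03 ± 0.49. The chemoreceptor-family genes sri-74 and sri-36 and the gene sdz-35 rose by 7.44, 6.46 and 6.57.

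Genes of fat and sugar metabolism fell in hlh-30 mutants in ARD. Of 20 genes of fatty acid synthesis and desaturation, 15 fell and 2 rose, as many adjusted over the list alone (median log2 change -0.89, camera adjusted p = 1.41e-08, adjusted p = 0.0478 with an estimated correlation). The desaturase genes fat-2 (-2.17 ± 0.10) and fat-5 (-2.87 ± 0.19) were among them. Of 19 genes of gluconeogenesis, the glyoxylate cycle and trehalose synthesis, 15 fell and 1 rose, as many adjusted over the list alone (median -0.52, adjusted p = 2.64e-08, and adjusted p = 0.0478 with an estimated correlation). They included icl-1, the glyoxylate cycle enzyme (-4.42 ± 0.22), and pck-2, a phosphoenolpyruvate carboxykinase (-2.2 ± 0.08). Of 29 beta-oxidation genes, 17 fell and 1 rose, as many adjusted over the list alone (median -0.75, adjusted p = 1.93e-05, but adjusted p = 0.388 with an estimated correlation). They included acs-2 (-3.64 ± 0.27) and hacd-1 (-3.48 ± 0.25). Of 19 DAF-16 and insulin-signalling responsive genes 11 fell and 1 rose, with 12 lower adjusted over the list alone (median -0.71, adjusted p = 7.62e-08, adjusted p = 0.204 with an estimated correlation). The linker histone gene hil-1 changed by -3.01 ± 0.21 and nnt-1 by -3.77 ± 0.28. Ribosomal protein genes fell in 64 of 77 cases and rose in 1, 65 and 1 adjusted over the list alone, by a smaller margin (median -0.34, adjusted p = 6.42e-11, adjusted p = 0.875 with an estimated correlation). Oxidative phosphorylation genes fell in 36 of 43 cases and rose in 1, 37 and 1 adjusted over the list alone (median -0.54, adjusted p = 6.28e-16, adjusted p = 0.395 with an estimated correlation). Intestinal markers rose in 8 of 14 cases and fell in 4, with 9 higher adjusted over the list alone (median 0.58, adjusted p = 0.0212, adjusted p = 0.875 with an estimated correlation). The intermediate filament organizer ifo-1 rose by 2.54 ± 0.14. Of 37 sperm genes 18 fell, as many adjusted over the list alone (median -1.23, adjusted p = 0.0472, adjusted p = 0.942 with an estimated correlation). The call was lost without N2 in ARD replicate 2 (adjusted p = 0.179), 3 (0.0846) or 4 (0.0595) and without hlh-30 in ARD replicate 1 (0.065) or 4 (0.0509). TFEB proteins are known regulators of autophagy and lysosomes: of 25 autophagy genes 4 were higher and 11 lower, and of 29 genes of lysosomal hydrolases and membrane proteins 9 were higher and 12 lower, and neither list passed (adjusted p = 0.233 and 0.0562). In all, 8140 of 17996 genes passed (4331 higher, 3809 lower), and 12463 did with library weights, an alternative added after the data were seen.

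**Figure D3:**
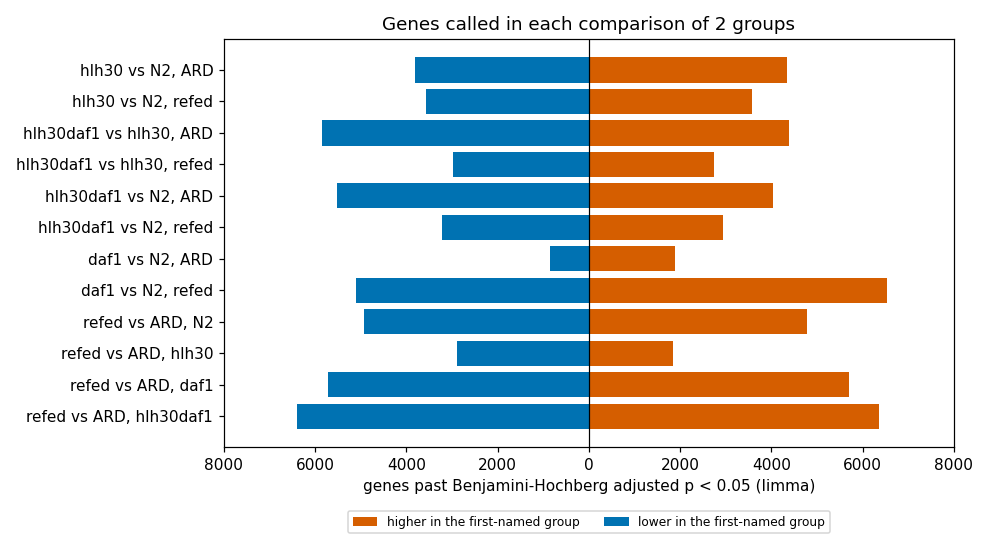
Number of genes past a limma adjusted p of 0.05 in each of the 12 comparisons of 2 groups, with those higher in the first-named group to the right and those lower to the left. The counts run from 2743 for daf-1 mutants against N2 in ARD to 12750 for refeeding of the double mutant.

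After refeeding, the same comparison asked which differences between hlh-30 mutants and N2 were found once food was back. Several of the genes named in ARD were named again: parg-2 was at 7356 ± 1173 normalized counts (SD, n = 3) in refed hlh-30 mutants against 16 ± 6.9 (n = 4) in N2 (log2 change 8.81 ± 0.50, adjusted p = 2.67e-13), and rab-11.2 (8.10 ± 0.48), cng-1 (7.64 ± 0.40), sri-36 (8.62 ± 0.53) and sri-74 (7.35 ± 0.85) were also higher. The P-glycoprotein transporter gene pgp-7 (7.96 ± 0.45) and srw-86 (7.89 ± 0.56) rose too, and the saposin-like gene spp-20 stood at 224 ± 33.4 in the mutants and was listed at 0 in all 4 N2 libraries. The flavin-containing monooxygenase gene fmo-2 fell from 738 ± 111 to 7.4 ± 2.9 (log2 change -6.51 ± 0.35, adjusted p = 1.18e-13). The RNA tts-1 fell by 6.03 ± 0.29 (adjusted p = 1.29e-14) and the lysozyme gene lys-5 by 5.58 ± 0.62. The other genes with the largest falls under the rule were the collagen genes col-88, col-161, col-156, col-162 and col-110, with log2 changes from -7.82 to -5.46.

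Cuticle and molting genes were lower in refed hlh-30 mutants. Of 162 cuticle collagen genes 87 fell and 15 rose, or 93 and 20 adjusted over the list alone (median -1.45, camera adjusted p = 0.000542, adjusted p = 0.936 with an estimated correlation). Of 35 molting cycle genes 25 fell and 2 rose, or 25 and 3 adjusted over the list alone (median -2.36, adjusted p = 0.000101, adjusted p = 0.936 with an estimated correlation). They included the protease gene nas-37 (-2.2 ± 0.31) and the transcription factor genes grh-1 (-1.35 ± 0.20) and nhr-23 (-0.78 ± 0.10). Ribosomal protein genes fell in 75 of 77 cases and rose in 1, as many adjusted over the list alone (median -0.44, adjusted p = 1.46e-19, adjusted p = 0.76 with an estimated correlation). ER unfolded protein response genes fell in 15 of 23 cases, as many adjusted over the list alone (median -0.76, adjusted p = 1.68e-06, adjusted p = 0.76 with an estimated correlation). They included the protein disulfide isomerase gene pdi-2 (-2.19 ± 0.22). Of 29 beta-oxidation genes 15 fell and 3 rose, 16 lower adjusted over the list alone (median -0.52, adjusted p = 0.000118, adjusted p = 0.76 with an estimated correlation). The carnitine palmitoyltransferase gene cpt-5 changed by -2.24 ± 0.20. Of 14 genes of the mitochondrial unfolded protein response 7 fell and 1 rose, as many adjusted over the list alone (median -0.26, adjusted p = 0.0251, adjusted p = 0.83 with an estimated correlation). Among them, the chaperonin gene hsp-60 changed by -1.34 ± 0.08. Autophagy genes were higher in 9 and lower in 2 of 25 cases and the list did not pass (adjusted p = 0.088). In all 7134 genes passed (3565 higher, 3569 lower), and 11333 with library weights. Of the genes called in ARD, 4022 were also called in the same direction after refeeding, where independence would give 858 higher and 755 lower, and 589 were called in the opposite direction.

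Comparing the double mutant with hlh-30 mutants in ARD asked what loss of daf-1 changed in worms without hlh-30. The genes with the largest rises under the rule were mostly cuticle genes: col-2 went from 10.1 ± 7.7 normalized counts to 2579 ± 2304 (SD, n = 4 each; log2 change 7.65 ± 1.0, adjusted p = 6.01e-07), and col-36, col-40, col-84, col-43, col-108 and the ground-like gene grl-20 rose by 6.43 to 7.34. The chitinase-like chil-28, which had fallen in hlh-30 mutants, rose from 25.9 ± 8.7 to 2017 ± 920 (6.18 ± 0.43, adjusted p = 1.3e-11). Several genes that were high in hlh-30 mutants fell: tbb-6 went from 8281 ± 2186 to 319 ± 81 (log2 change -4.69 ± 0.23, adjusted p = 1.41e-14), sdz-35 changed by -6.38 ± 0.54, sri-74 by -6.12 ± 0.79 and sri-36 by -4.86 ± 0.49. The ADP-ribosylation factor gene arf-1.1 (-5.49 ± 0.35) and the sirtuin gene sir-2.3 (-4.87 ± 0.32) fell as well. The metal-responsive paralogs numr-1 and numr-2 had the same values in every library (-4.55 ± 0.46), so which of them changed is uncertain.

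Metabolic and lysosomal genes rose in the double mutant in ARD. Of 20 fatty acid synthesis and desaturation genes 15 rose and 1 fell, 15 and 2 adjusted over the list alone (median 1.17, camera adjusted p = 3.7e-11, adjusted p = 0.025 with an estimated correlation). Among them, fat-2 changed by 1.78 ± 0.10. Of 19 gluconeogenesis, glyoxylate and trehalose genes 14 rose, as many adjusted over the list alone (median 0.62, adjusted p = 2.75e-10, adjusted p = 0.025 with an estimated correlation). Among them, icl-1 changed by 3.57 ± 0.22 and pck-2 by 2.18 ± 0.08. Lipase genes rose in 7 of 13 cases and fell in 1, as many adjusted over the list alone (median 2.19, adjusted p = 0.000177, adjusted p = 0.0744 with an estimated correlation). They included lipl-3 (5.01 ± 0.37) and lipl-4 (4.30 ± 0.34). Genes of lysosomal hydrolases and membrane proteins rose in 17 of 29 cases and fell in 8, as many adjusted over the list alone (median 0.52, adjusted p = 1.49e-06, adjusted p = 0.176 with an estimated correlation). They included the aspartyl protease gene asp-3 (2.52 ± 0.14) and the cathepsin gene cpr-1 (3.31 ± 0.20). V-ATPase genes rose in 18 of 21 cases and fell in 3, as many adjusted over the list alone (median 0.61, adjusted p = 1.2e-10, adjusted p = 0.188 with an estimated correlation). Collagen genes rose in 136 of 162 cases and fell in 6, or 144 and 7 adjusted over the list alone (median 2.43, adjusted p = 2.07e-13, adjusted p = 0.26 with an estimated correlation). Innate defence genes rose too: 75 of 149 C-type lectin genes rose and 17 fell, 75 and 18 adjusted over the list alone (median 0.76, adjusted p = 6.19e-12, adjusted p = 0.0744 with an estimated correlation). 46 of 86 antimicrobial and pathogen response genes rose and 12 fell, as many adjusted over the list alone (median 0.77, adjusted p = 6.32e-08, adjusted p = 0.279 with an estimated correlation). Among them, the lysozyme gene lys-7 changed by 3.33 ± 0.16.

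Germline genes moved the other way in the same comparison. All 28 genes of the oocyte and early embryo list fell, as many adjusted over the list alone (median -1.64, adjusted p = 0.000396, adjusted p = 0.547 with an estimated correlation). They included cav-1 (-2.84 ± 0.56) and mex-5 (-1.77 ± 0.37). Of 35 genes of germ cells and meiosis 32 fell, as many adjusted over the list alone (median -0.59, adjusted p = 0.000354, adjusted p = 0.547 with an estimated correlation). All 37 DNA replication and cell cycle genes fell, as many adjusted over the list alone (median -0.62, adjusted p = 0.000177, adjusted p = 0.547 with an estimated correlation). In all 10248 of 17996 genes passed, with 4392 higher and 5856 lower, and 2289 of the higher and 1439 of the lower genes changed at least 2-fold.

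In the refed worms the double mutant was compared with hlh-30 mutants in the same way. The lipase gene lipl-3 was at 159 ± 12 normalized counts (SD, n = 4) against 6.3 ± 4.2 (n = 3), a log2 change of 4.59 ± 0.40 (adjusted p = 1.22e-09). The genes math-34 (6.13 ± 0.32), lips-14 (5.83 ± 0.60, annotated as a pseudogene), chil-28 (5.38 ± 0.47), dod-3 (4.77 ± 0.42), clec-169 (4.11 ± 0.32), fbxa-172 (3.89 ± 0.24) and the carnitine palmitoyltransferase gene cpt-3 (3.84 ± 0.58) were higher. The tubulin gene tbb-6 fell from 4623 ± 1092 to 73.1 ± 13.2 (log2 change -5.95 ± 0.25, adjusted p = 1.76e-15), beside 57.3 ± 6.9 in refed N2. The chemoreceptor-family genes sri-74 and sri-36, rab-11.2, lys-3, pgp-7, the infection response gene irg-2 and sdz-35 also fell, with log2 changes from -7.43 to -5.81.

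Among gene groups, 20 of 29 beta-oxidation genes rose and 1 fell, 22 and 1 adjusted over the list alone (median 0.81, camera adjusted p = 2.47e-09, adjusted p = 0.137 with an estimated correlation). Among them, the acyl-CoA oxidase gene acox-1.2 changed by 2.25 ± 0.12 and cpt-5 by 2.34 ± 0.20. Oxidative phosphorylation genes rose in 40 of 43 cases, as many adjusted over the list alone (median 0.50, adjusted p = 9.42e-23, adjusted p = 0.202 with an estimated correlation). Autophagy genes fell in 9 of 25 cases and rose in 1, 10 lower adjusted over the list alone (median -0.15, adjusted p = 0.00257, adjusted p = 0.484 with an estimated correlation), led by the cargo receptor gene sqst-1 (-3.41 ± 0.18), and lgg-1 changed by -0.81 ± 0.10. Ribosomal protein genes rose in 33 of 77 cases and fell in 1, 39 and 1 adjusted over the list alone (median 0.19, adjusted p = 0.000113, adjusted p = 0.774 with an estimated correlation). With quantile normalization the median was -0.08 and the list passed in the other direction (adjusted p = 0.00328). Of 162 collagen genes 42 rose and 5 fell, 40 and 5 adjusted over the list alone (median 0.28, adjusted p = 0.018, adjusted p = 0.83 with an estimated correlation). Without double mutant refed replicate 1 the median was -0.21 and the call was lost (adjusted p = 0.284). In all 5720 genes passed (2743 higher, 2977 lower), and 10098 with library weights.

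The changes of hlh-30 mutants that loss of daf-1 moved back were counted. In ARD, 4888 of the 8140 genes called between hlh-30 mutants and N2 (60%) were called in the opposite direction between the double mutant and hlh-30 mutants: 2568 of the genes higher and 2320 of those lower in hlh-30 mutants, where independence would give 1409 and 930. Another 679 genes moved further in the same direction. Of the genes moved back, 2953 did not pass the threshold between the double mutant and N2, which does not show that they were equal. The 2 comparisons share the hlh-30 libraries with opposite sign. The covariance of their log2 changes over genes was -0.65 (correlation -0.55), against -0.05 (correlation -0.50) in 20 simulations of unchanged groups. The simulations hold almost no called genes by construction, so their joint count of 0 does not measure what the shared libraries add. With the 4 hlh-30 libraries divided between the 2 comparisons, 3465 to 3675 genes were counted over 6 divisions, and the covariance was -0.62. After refeeding 3333 of 7134 genes (46.7%) moved back, 1886 of the higher and 1447 of the lower, where independence would give 590 and 544, and 383 moved further. Library weights raised that count to 6279. With 3 refed hlh-30 libraries no such division was made, so part of this count may come from the shared libraries. The covariance was -0.47 (correlation -0.49), against -0.07 (correlation -0.57) in the simulations.

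The double mutant was also compared with N2 to show what remained different. In ARD, fbxa-24 was at 13.7 ± 2.41 normalized counts (SD, n = 4) against 3910 ± 441 in N2 (log2 change -8.07 ± 0.25, adjusted p = 3.34e-18), and tts-1 was at 6262 ± 3562 against 373232 ± 35340 (-6.05 ± 0.27, adjusted p = 3.3e-15). The genes cpr-2 (-5.82 ± 0.47) and fbxa-21 (-4.35 ± 0.24, annotated as a pseudogene) were lower as well. The collagen genes col-36, col-2, col-43 and col-40 had the largest rises under the rule, from 8.75 to 9.56 on the log2 scale. Antimicrobial and pathogen response genes rose in 51 of 86 cases and fell in 8, 52 and 8 adjusted over the list alone (median 1.25, camera adjusted p = 3.27e-12, adjusted p = 0.29 with an estimated correlation). Among them, lys-7 changed by 3.01 ± 0.16. Body wall muscle markers rose in 19 of 21 cases, as many adjusted over the list alone (median 1.16, adjusted p = 3.51e-18, adjusted p = 0.29 with an estimated correlation). Among them, the troponin gene tnt-2 changed by 3.39 ± 0.19. Autophagy genes fell in 15 of 25 cases and rose in 3, as many adjusted over the list alone (median -0.38, adjusted p = 0.00084, adjusted p = 0.29 with an estimated correlation). They included atg-18 (-1.12 ± 0.10) and epg-9 (-1.75 ± 0.17). Ribosomal protein genes fell in 75 of 77 cases, as many adjusted over the list alone (median -0.44, adjusted p = 1.16e-22, adjusted p = 0.331 with an estimated correlation). Sperm genes fell in 31 of 37 cases, 35 adjusted over the list alone (median -2.05, adjusted p = 1.26e-05, adjusted p = 0.671 with an estimated correlation). The oocyte and early embryo list fell in 24 of 28 cases, 25 adjusted over the list alone (median -1.28, adjusted p = 0.00104, adjusted p = 0.671 with an estimated correlation). Without the 3 libraries that stood apart the median was -0.44 and the call was lost (adjusted p = 0.0659). In all 9559 genes passed, 4036 higher and 5523 lower; a fit of the 2 groups alone called 5221, with 2930 higher and 2291 lower.

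The double mutant and N2 were compared likewise after refeeding. The C-type lectin gene clec-60 was at 6950 ± 2490 normalized counts (SD, n = 4) against 20.5 ± 10.4 (log2 change 8.43 ± 0.32, adjusted p = 4.91e-16), and the paralogs clec-13 and clec-15, whose values are the same in every library, rose by 7.19 ± 0.33. The gene lips-14 rose by 6.54 ± 0.56. The genes lys-5 (-6.91 ± 0.57) and fmo-2 (-6.42 ± 0.33) fell, as did the collagen genes rol-6 (-5.72 ± 1.24, adjusted p = 0.000669) and sqt-1 (-5.91 ± 1.33, adjusted p = 0.000959, but 0.0543 in a fit of the 2 groups alone). Of 149 C-type lectin genes 71 rose and 19 fell, 71 and 20 adjusted over the list alone (median 0.57, camera adjusted p = 4.14e-10, adjusted p = 0.334 with an estimated correlation). Molting cycle genes fell in 26 of 35 cases and rose in 3, as many adjusted over the list alone (median -2.76, adjusted p = 6.13e-08, adjusted p = 0.59 with an estimated correlation). Among them, the fibrillin-like gene fbn-1 changed by -3.78 ± 0.44. Xenobiotic detoxification genes rose in 70 of 176 cases and fell in 25, 73 and 25 adjusted over the list alone (median 0.38, adjusted p = 0.000126, adjusted p = 0.59 with an estimated correlation). Of 19 DAF-16 and insulin-signalling responsive genes 10 rose and 1 fell, 10 and 2 adjusted over the list alone (median 0.63, adjusted p = 0.000204, adjusted p = 0.503 with an estimated correlation). Among them, the superoxide dismutase gene sod-3 changed by 3.00 ± 0.23 and tts-1 by -4.79 ± 0.27. In all 6158 genes passed (2930 higher, 3228 lower), and 9249 with library weights.

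Loss of daf-1 with hlh-30 intact was compared with N2 in ARD. The insulin-like peptide gene ins-6 fell from 88.2 ± 26.7 normalized counts (SD, n = 4) to 6.21 ± 1.48 (n = 3), a log2 change of -3.61 ± 0.27 (adjusted p = 2.94e-09). The nematode-specific peptide genes nspc-7 (-3.90 ± 0.30), nspc-4 (-4.61 ± 0.53) and nspe-2 (-3.06 ± 0.48) also fell. The collagen genes col-36 (8.73 ± 1.28), col-43 (7.99 ± 0.89), col-84 (6.35 ± 1.09) and col-123 (5.93 ± 1.04) rose. Of 19 gluconeogenesis, glyoxylate and trehalose genes 11 rose, 12 adjusted over the list alone (median 0.44, camera adjusted p = 1.75e-09, adjusted p = 0.0594 with an estimated correlation). Among them, pck-1 changed by 0.96 ± 0.10. V-ATPase genes rose in 17 of 21 cases, 18 adjusted over the list alone (median 0.27, adjusted p = 2.86e-07, adjusted p = 0.449 with an estimated correlation). Autophagy genes rose in 7 of 25 cases, 9 adjusted over the list alone (median 0.23, adjusted p = 0.000602, adjusted p = 0.33 with an estimated correlation). Fatty acid synthesis and desaturation genes rose in 10 of 20 cases, with 11 higher and 1 lower adjusted over the list alone (median 0.32, adjusted p = 2.06e-06, adjusted p = 0.231 with an estimated correlation). Cytosolic heat shock genes rose in 11 of 23 cases, 15 adjusted over the list alone (median 0.60, adjusted p = 0.000144, adjusted p = 0.506 with an estimated correlation). Among them, hsp-70 changed by 2.89 ± 0.65, but its groups overlapped and the call was lost in a fit of the 2 groups alone (adjusted p = 0.0732). Ribosome biogenesis and RNA polymerase I genes fell in 10 of 33 cases, 19 adjusted over the list alone (median -0.21, adjusted p = 1.75e-09, adjusted p = 0.506 with an estimated correlation). The 4 vitellogenin genes, which encode yolk proteins, gave 3 that rose, as many adjusted over the list alone (median 2.65, adjusted p = 0.0203, adjusted p = 0.506 with an estimated correlation). The call was lost without N2 in ARD replicate 1 (adjusted p = 0.137) or daf-1 in ARD replicate 1 (0.0625). Of 28 oocyte and early embryo genes 2 rose, 17 adjusted over the list alone (median 1.07, adjusted p = 0.000625, adjusted p = 0.778 with an estimated correlation). That call was lost without N2 in ARD replicate 1 (median 0.64, adjusted p = 0.0853). The mean log2 level of the vitellogenins ran from 6.37 to 10.83 over the N2 libraries in ARD. In all 2743 genes passed (1887 higher, 856 lower), and 1569 and 1715 without daf-1 in ARD replicates 4 and 2. The count was 677 in a fit of the 2 groups alone, 4841 without the libraries that stood apart and 7595 with library weights, and with quantile normalization it was 1571 higher and 1713 lower.

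The same comparison after refeeding called 11643 genes, 6531 higher and 5112 lower in daf-1 mutants. The genes pud-4 and pud-3, named for proteins raised in daf-2 mutants, rose by 6.97 ± 0.41 (from 1.62 ± 1.39 to 290 ± 58.1 normalized counts, SD, n = 4 each, adjusted p = 1.31e-12) and 6.15 ± 0.70, and chil-28 (6.57 ± 0.43) and the neuropeptide-like gene nlp-39 (6.60 ± 0.82) rose with them. The collagen genes col-88 (-8.88 ± 0.96), col-161 (-7.62 ± 1.03) and col-133 (-6.11 ± 0.64) and the gene nspc-4 (-6.44 ± 0.49) fell. Autophagy genes rose in 22 of 25 cases and fell in 1, as many adjusted over the list alone (median 0.91, camera adjusted p = 2.36e-11, adjusted p = 0.0694 with an estimated correlation). They included lgg-1 (1.55 ± 0.09) and atg-13 (1.32 ± 0.08). Of 19 DAF-16 and insulin-signalling responsive genes 18 rose, as many adjusted over the list alone (median 2.16, adjusted p = 4.98e-09, adjusted p = 0.0975 with an estimated correlation). Among them, dod-3 changed by 5.37 ± 0.39 and nnt-1 by 3.91 ± 0.28. Gluconeogenesis, glyoxylate and trehalose genes rose in 15 of 19 cases and fell in 1, as many adjusted over the list alone (median 0.84, adjusted p = 3.36e-07, adjusted p = 0.0975 with an estimated correlation). All 28 oocyte and early embryo genes rose, as many adjusted over the list alone (median 1.84, adjusted p = 0.000311, adjusted p = 0.943 with an estimated correlation). Among them, cav-1 changed by 4.01 ± 0.56. By contrast 36 of 37 sperm genes fell, as many adjusted over the list alone (median -2.67, adjusted p = 7.07e-09, adjusted p = 0.943 with an estimated correlation). Among them, fer-1 changed by -3.44 ± 0.38. All 37 DNA replication and cell cycle genes rose, as many adjusted over the list alone (median 0.93, adjusted p = 6.29e-07, adjusted p = 0.943 with an estimated correlation). 21 of 26 DNA damage and apoptosis genes rose and 1 fell, as many adjusted over the list alone (median 0.60, adjusted p = 0.00261, adjusted p = 0.943 with an estimated correlation). Ribosomal protein genes fell in 76 of 77 cases, as many adjusted over the list alone (median -0.45, adjusted p = 4.93e-20, adjusted p = 0.855 with an estimated correlation).

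Refeeding of N2 asked what changed as worms left ARD. All 4 vitellogenin genes rose, as many adjusted over the list alone (median 5.12, camera adjusted p = 0.00776, adjusted p = 0.627 with an estimated correlation). Of 86 antimicrobial and pathogen response genes 27 rose and 36 fell, 27 and 38 adjusted over the list alone, and the list did not pass (median -0.39, mean -0.04, test direction upward, adjusted p = 0.969). The vitellogenin gene vit-1 went from 12 ± 10 to 1554 ± 557 normalized counts (SD, n = 4 each; log2 change 7.30 ± 0.48, adjusted p = 1.28e-12), and the saposin-like gene spp-17 from 120 ± 37 to 4246 ± 596 (5.19 ± 0.22, adjusted p = 2.54e-16). The genes spp-23 (7.37 ± 0.53), vit-5 (5.99 ± 0.79), the lysozyme genes ilys-5 (5.22 ± 0.21) and lys-4 (4.57 ± 0.30), scl-6 (4.75 ± 0.36) and the acid phosphatase gene pho-13 (4.69 ± 0.19) rose as well. The metallothionein gene mtl-1 fell from 1471 ± 805 to 2.6 ± 1.0 (log2 change -8.53 ± 0.43, adjusted p = 7.84e-15) and tts-1 from 373232 ± 35340 to 3939 ± 489 (-6.57 ± 0.27, adjusted p = 1.88e-16). The genes chil-28, fbxa-164, cyp-35B1 (a cytochrome P450 gene), arrd-11 (an arrestin-domain gene), alh-2 and nnt-1 (a mitochondrial transhydrogenase gene) also fell, with log2 changes from -8.72 to -6.40. The transcript of hlh-30 itself fell by 1.11 ± 0.17 (adjusted p = 4.39e-06).

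All 19 DAF-16 and insulin-signalling responsive genes fell on refeeding of N2, as many adjusted over the list alone (median -3.80, camera adjusted p = 1.73e-24, adjusted p = 0.00823 with an estimated correlation). Among them, hil-1 changed by -5.53 ± 0.21 and sod-3 by -5.22 ± 0.23. Autophagy genes fell in 20 of 25 cases and rose in 1, 21 and 1 adjusted over the list alone (median -0.69, adjusted p = 6.22e-07, adjusted p = 0.0508 with an estimated correlation). Among them, lgg-2 changed by -1.64 ± 0.10 and atg-16.2 by -1.5 ± 0.07. Lipase genes fell in 7 of 13 cases and rose in 2, as many adjusted over the list alone (median -1.27, adjusted p = 0.0127, adjusted p = 0.283 with an estimated correlation). Among them, lipl-3 changed by -4.67 ± 0.37. V-ATPase genes rose in 19 of 21 cases, 20 adjusted over the list alone (median 0.82, adjusted p = 9.5e-19, adjusted p = 0.17 with an estimated correlation). Among them, vha-12 changed by 1.79 ± 0.08. Protein synthesis and folding genes rose: 73 of 77 ribosomal protein genes rose and 1 fell, 74 and 1 adjusted over the list alone (median 0.31, adjusted p = 1.5e-07, adjusted p = 0.72 with an estimated correlation). 17 of 23 genes of the ER unfolded protein response rose and 2 fell, 19 and 2 adjusted over the list alone (median 1.11, adjusted p = 6.65e-09, adjusted p = 0.273 with an estimated correlation). 10 of 14 genes of the mitochondrial unfolded protein response rose and 2 fell, 11 and 2 adjusted over the list alone (median 0.50, adjusted p = 0.0006, adjusted p = 0.283 with an estimated correlation). Among them, hsp-60 changed by 2.3 ± 0.08. Molting cycle genes rose in 26 of 35 cases and fell in 2, 27 and 2 adjusted over the list alone (median 1.87, adjusted p = 0.00258, adjusted p = 0.728 with an estimated correlation). Intestinal markers rose in 8 of 14 cases and fell in 3, as many adjusted over the list alone (median 0.81, adjusted p = 0.000399, adjusted p = 0.627 with an estimated correlation). Among them, the actin gene act-5 changed by 3.49 ± 0.11. Neuron markers fell in 19 of 33 cases and rose in 3, 20 and 3 adjusted over the list alone (median -0.47, adjusted p = 0.00139, adjusted p = 0.728 with an estimated correlation). Among them, nlp-21 changed by -2.0 ± 0.10. Oxidative phosphorylation genes rose in 24 of 43 cases and fell in 2, as many adjusted over the list alone (median 0.22, adjusted p = 0.00179, adjusted p = 0.728 with an estimated correlation). With quantile normalization the median was -0.01 and the call was lost (adjusted p = 0.601). In all 9725 genes passed, 4788 higher and 4937 lower.

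Refeeding of hlh-30 mutants was compared in the same way. The gene spp-17 rose from 11.6 ± 5.2 (SD, n = 4) to 2536 ± 356 normalized counts (n = 3), a log2 change of 7.73 ± 0.23 (adjusted p = 2.86e-18), and daf-36, an oxygenase gene of dafachronic acid synthesis, from 20.9 ± 7.2 to 598 ± 64.7 (4.83 ± 0.29, adjusted p = 2.5e-12). The tryptophan dioxygenase gene tdo-2 (5.57 ± 0.18), the glucuronosyltransferase gene ugt-63 (5.79 ± 0.55), irg-4 (5.55 ± 0.25), dct-17 (5.33 ± 0.25), spp-23 (5.29 ± 0.57) and pho-13 (5.12 ± 0.20) rose too. The genes mtl-1 (-4.91 ± 0.46), sod-3 (-3.98 ± 0.25), cyp-35B1, cyp-35B2, cyp-35B3 and cyp-37B1 fell, the P450 genes by -4.44 to -3.36, and the paralogs clec-13 and clec-15 with shared values fell by 3.76 ± 0.36. V-ATPase genes rose in 18 of 21 cases, as many adjusted over the list alone (median 0.69, camera adjusted p = 8.23e-31, adjusted p = 0.0415 with an estimated correlation). Of 19 DAF-16 and insulin-signalling responsive genes 15 fell and 1 rose, 17 and 1 adjusted over the list alone (median -1.65, adjusted p = 2e-14, adjusted p = 0.0316 with an estimated correlation). Beta-oxidation genes rose in 11 of 29 and fell in 2, as many adjusted over the list alone (median 0.51, adjusted p = 2.7e-05, adjusted p = 0.368 with an estimated correlation). Among them, the acyl-CoA oxidase gene acox-1.4 changed by 3.48 ± 0.23. In all 4732 genes passed (1831 higher, 2901 lower); a fit of the 2 groups alone called 8537 and library weights gave 9384. Of the genes called in N2, 3434 were also called here in the same direction, where independence would give 487 higher and 796 lower, and 344 in the opposite direction.

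Refeeding of daf-1 mutants raised vit-1 from 13.3 ± 2.8 (SD, n = 3) to 5959 ± 1955 normalized counts (n = 4; log2 change 8.66 ± 0.51, adjusted p = 4.8e-13), with spp-23 (5.83 ± 0.57), lips-14 (5.60 ± 0.60) and ilys-5 (5.45 ± 0.23). The collagen genes col-88, col-50, col-84 and col-161 fell, with log2 changes from -8.38 to -7.37. All 4 vitellogenin genes rose, as many adjusted over the list alone (median 4.53, camera adjusted p = 0.00463, adjusted p = 0.616 with an estimated correlation). Of 19 DAF-16 and insulin-signalling responsive genes 17 fell, 18 adjusted over the list alone (median -1.90, adjusted p = 4.07e-10, adjusted p = 0.128 with an estimated correlation). Of 35 genes of germ cells and meiosis 33 rose, as many adjusted over the list alone (median 0.85, adjusted p = 9.96e-06, adjusted p = 0.616 with an estimated correlation). Of 37 DNA replication and cell cycle genes 36 rose, as many adjusted over the list alone (median 0.99, adjusted p = 1.68e-07, adjusted p = 0.616 with an estimated correlation). Fatty acid synthesis and desaturation genes fell in 10 of 20 cases and rose in 6, 11 and 6 adjusted over the list alone (median -0.42, adjusted p = 0.000591, adjusted p = 0.616 with an estimated correlation). Among them, fat-3 changed by -3.08 ± 0.13. Ribosome biogenesis and RNA polymerase I genes rose in 28 of 33 cases and fell in 4, as many adjusted over the list alone (median 0.41, adjusted p = 0.0047, adjusted p = 0.718 with an estimated correlation). With quantile normalization the test turned in direction and did not pass (median 0.13, adjusted p = 0.771). Insulin-like peptide genes fell in 16 of 32 cases and rose in 6, as many adjusted over the list alone (median -0.91, adjusted p = 0.0428, adjusted p = 0.709 with an estimated correlation). That call was lost with quantile normalization (adjusted p = 0.379) and without daf-1 in ARD replicate 1 (0.0556) or 2 (0.0603) or daf-1 refed replicate 2 (0.0579) or 3 (0.0548). The median change of all genes was -0.12 here and 0.06 with quantile normalization. In all 11409 genes passed, 5694 higher and 5715 lower, and 6054 genes were called in the same direction as in N2, where independence would give 1515 higher and 1568 lower.

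Refeeding of the double mutant called the most genes of the 16 comparisons, 12750, with 6347 higher and 6403 lower. The vitellogenin gene vit-5 rose from 1070 ± 936 to 51000 ± 11900 normalized counts (SD, n = 4 each; log2 change 6.19 ± 0.79, adjusted p = 2.7e-07), and vit-1 (5.99 ± 0.48), lips-14 (7.39 ± 0.56) and ugt-63 (6.49 ± 0.51) rose too. The collagen genes col-2, col-108, col-50 and col-85 fell, with log2 changes from -7.14 to -5.71. Of 162 collagen genes 106 fell and 7 rose, as many adjusted over the list alone (median -1.87, camera adjusted p = 1.95e-05, adjusted p = 0.473 with an estimated correlation). Of 37 sperm genes 36 rose, as many adjusted over the list alone (median 2.71, adjusted p = 2.01e-05, adjusted p = 0.473 with an estimated correlation). 27 of 28 oocyte and early embryo genes rose, as many adjusted over the list alone (median 2.56, adjusted p = 1.38e-05, adjusted p = 0.473 with an estimated correlation). Mitochondrial unfolded protein response genes rose in 11 of 14 cases and fell in 2, as many adjusted over the list alone (median 0.77, adjusted p = 1.41e-06, adjusted p = 0.332 with an estimated correlation). Among them, hsp-60 changed by 3.25 ± 0.08. Of 19 DAF-16 and insulin-signalling responsive genes 17 fell, as many adjusted over the list alone (median -2.66, adjusted p = 1.19e-12, adjusted p = 0.0995 with an estimated correlation). TGF-beta pathway genes fell in 17 of 25 cases, as many adjusted over the list alone (median -0.55, adjusted p = 0.00354, adjusted p = 0.473 with an estimated correlation). Among them, the type II receptor gene daf-4 changed by -0.96 ± 0.10. Pharynx markers fell in 14 of 15 cases and rose in 1, as many adjusted over the list alone (median -1.0, adjusted p = 0.00654, adjusted p = 0.473 with an estimated correlation). C-type lectin genes fell in 61 of 149 cases and rose in 42, as many adjusted over the list alone (median -0.28, adjusted p = 0.0413, adjusted p = 0.569 with an estimated correlation). The call was lost with a replicate block (adjusted p = 0.0522), with quantile normalization (0.105), without the double mutant in ARD replicate 2 (0.0664) or 4 (0.0552) and without its refed replicate 2 (0.0644). Of the genes called in N2, 6664 were also called here in the same direction, where independence would give 1689 higher and 1757 lower.

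**Figure D4:**
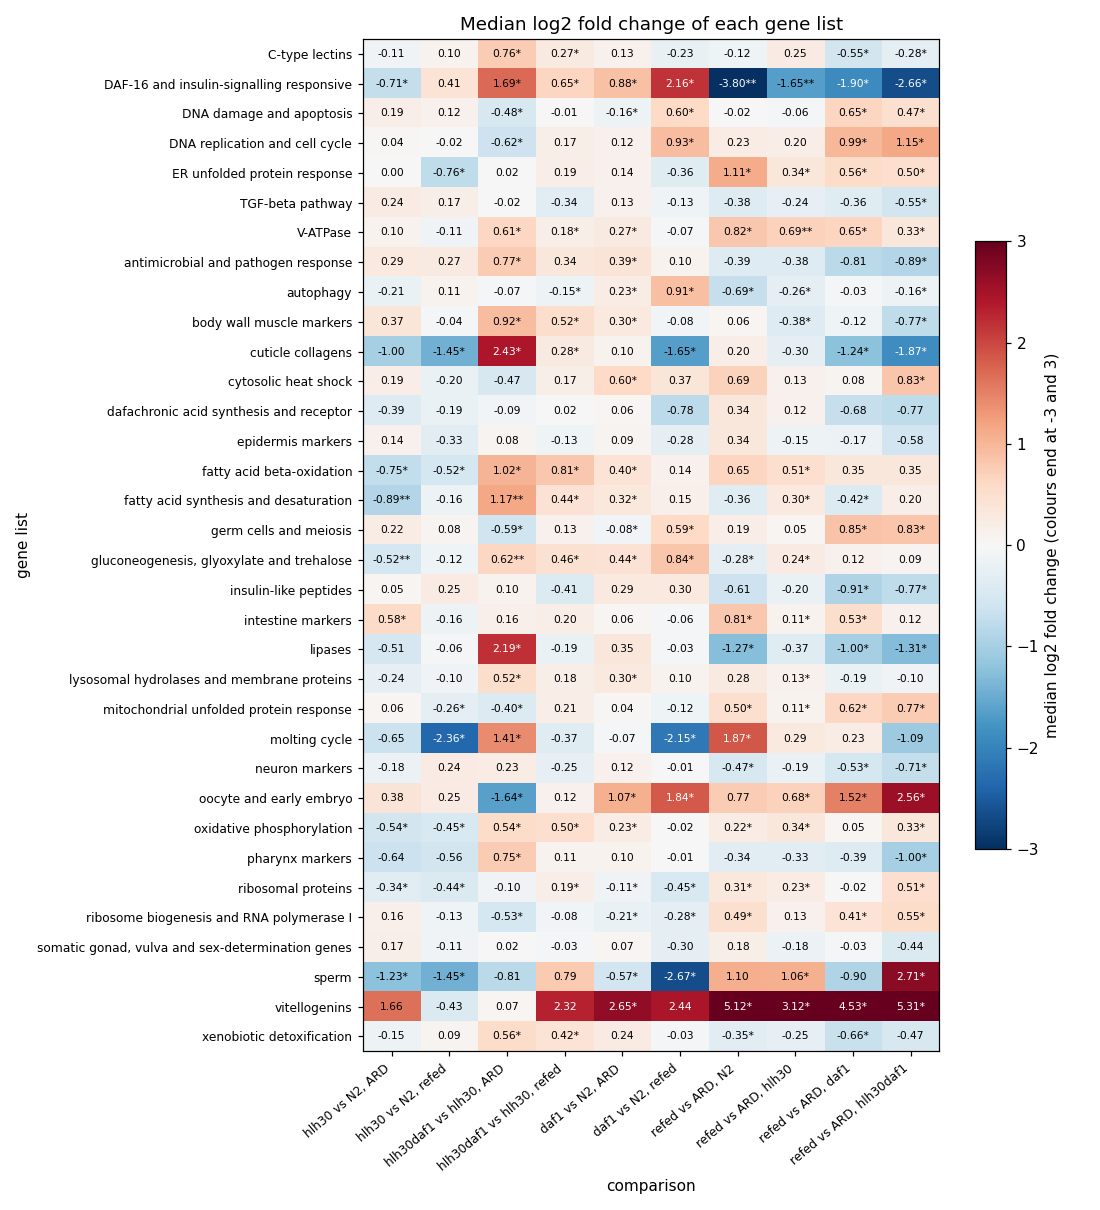
Median log2 fold change of each of the 34 gene lists in 10 comparisons, with the first-named group against the second; colours end at -3 and 3, * marks a camera adjusted p under 0.05 with the preset correlation and ** one that also passes with an estimated correlation. DAF-16 and insulin-signalling responsive genes stand at -3.80 on refeeding of N2 and at -1.65 on refeeding of hlh-30 mutants.

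Whether refeeding acted differently in hlh-30 mutants and in N2 was tested as an interaction, in which a positive value means a more positive change in the mutants. The changes of chil-28 (6.81 ± 0.64, adjusted p = 1.18e-08), cyp-34A9 (5.75 ± 0.43), fbxa-164 (5.57 ± 0.49) and cpr-2 (5.23 ± 0.70) were more positive in hlh-30 mutants, and those of lon-1 (-4.32 ± 0.36, adjusted p = 2.14e-09), scl-6 (-4.26 ± 0.53), mltn-9 (-3.99 ± 0.73) and vit-1 (-3.95 ± 0.70) more negative. DAF-16 and insulin-signalling responsive genes fell on refeeding in both genotypes, less in the mutants, where most were lower in ARD. Of 19, 14 had a positive interaction, 16 adjusted over the list alone (median 1.32, camera adjusted p = 8.88e-12, 0.0339 with an estimated correlation). Among them, icl-1 had an interaction of 4.62 ± 0.33 and hil-1 one of 3.42 ± 0.31. Gluconeogenesis, glyoxylate and trehalose genes had a positive interaction in 8 of 19 cases, 9 adjusted over the list alone (median 0.36, adjusted p = 2.01e-09, 0.0418 with an estimated correlation). Among them, pck-2 had a value of 2.35 ± 0.12. Autophagy genes had a positive one in 11 of 25 cases and a negative one in 1, 12 and 1 adjusted over the list alone (median 0.49, adjusted p = 6.37e-05, 0.0911 with an estimated correlation). Among them, lgg-2 had a value of 1.08 ± 0.14. ER unfolded protein response genes had a negative one in 14 of 23, 16 adjusted over the list alone (median -0.46, adjusted p = 1.14e-05, 0.394 with an estimated correlation). Among them, pdi-1 had a value of -1.04 ± 0.11. In all 4627 genes passed (2186 positive, 2441 negative), and 8670 with library weights.

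Refeeding changes of the double mutant and hlh-30 mutants were compared likewise. The interaction was positive for lips-14 (5.40 ± 0.82, adjusted p = 3.8e-05), cdc-25.3 (4.24 ± 1.18), rgs-9 (3.93 ± 1.15) and col-135 (3.54 ± 0.63), and negative for col-85 (-5.42 ± 0.73, adjusted p = 1e-05), col-2 (-6.13 ± 1.47), grl-20 (-5.81 ± 1.16) and grl-21 (-5.76 ± 1.5). Germline groups had positive values, with 25 of 35 genes of germ cells and meiosis, 27 adjusted over the list alone (median 0.70, camera adjusted p = 4.07e-07, adjusted p = 0.473 with an estimated correlation). So did 27 of 37 DNA replication and cell cycle genes, 37 adjusted over the list alone (median 0.81, adjusted p = 2.02e-07, 0.473 with an estimated correlation). Mitochondrial unfolded protein response genes had them in 10 of 14 cases, as many adjusted over the list alone (median 0.65, adjusted p = 3.65e-06, adjusted p = 0.24 with an estimated correlation). Among them, hsp-60 had a value of 1.37 ± 0.12. Lipase genes had negative values in 7 of 13 cases, as many adjusted over the list alone (median -1.35, adjusted p = 0.00119, 0.24 with an estimated correlation). Collagen genes had negative values in 56 of 162 cases, 59 adjusted over the list alone, and a positive one in 1 (median -1.93, adjusted p = 4.91e-08, adjusted p = 0.473 with an estimated correlation). In all 6345 genes passed, 3517 positive and 2828 negative.

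The effect of losing daf-1 was compared between worms without hlh-30 and worms with it, a positive value meaning a more positive effect without hlh-30. In ARD it was more positive for lipl-3 (5.67 ± 0.55, adjusted p = 1.81e-08), the acyl-CoA dehydrogenase gene acdh-1 (4.63 ± 0.38), the lysozyme gene lys-6 (4.42 ± 0.35) and the transporter gene pmp-5 (4.39 ± 0.27), and more negative for the Skp1-related gene skr-7 (-6.33 ± 1.34, adjusted p = 0.000691), sea-1 (-6.03 ± 1.25), srw-85 (-5.88 ± 0.65) and the collagen gene dpy-14 (-5.86 ± 1.09). Of 29 beta-oxidation genes 15 had a positive value and 3 a negative one, 16 and 3 adjusted over the list alone (median 0.80, camera adjusted p = 2.08e-06, adjusted p = 0.289 with an estimated correlation). All 28 oocyte and early embryo genes had negative values, as many adjusted over the list alone (median -2.79, adjusted p = 2.04e-07, adjusted p = 0.453 with an estimated correlation). Among them, mex-5 had a value of -2.75 ± 0.55. Of 149 C-type lectin genes 64 had a positive and 13 a negative value, 66 and 14 adjusted over the list alone (median 0.74, adjusted p = 1.05e-10, adjusted p = 0.2 with an estimated correlation). Cytosolic heat shock genes had negative values in 17 of 23 cases and positive ones in 2, 18 and 2 adjusted over the list alone (median -0.76, adjusted p = 0.000127, adjusted p = 0.453 with an estimated correlation). In all 6565 genes passed (2163 positive, 4402 negative), and 10259 with library weights. Of the genes called for loss of daf-1 with hlh-30 intact, 1347 were called in the same direction without hlh-30, where independence would give 461 higher and 279 lower, and 522 in the opposite direction (r = 0.22 across genes, which are not independent replicates).

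After refeeding the effect of losing daf-1 differed between the backgrounds for 10033 genes, 4570 positive and 5463 negative. Collagen genes led in both directions: col-88 (11.42 ± 1.41), col-161 (9.30 ± 1.51), col-133 (9.09 ± 0.95, adjusted p = 3.51e-08) and col-162 (8.16 ± 1.11) had positive values, and col-74 (-8.41 ± 1.28) and col-165 (-8.31 ± 1.06), with sri-36 (-8.32 ± 0.72) and the Skp1-related gene skr-8 (-8.09 ± 1.4), negative ones. Autophagy genes had negative values in 22 of 25 cases and a positive one in 1, as many adjusted over the list alone (median -1.01, camera adjusted p = 3.13e-14, adjusted p = 0.0299 with an estimated correlation). Among them, sqst-1 stood at -4.23 ± 0.25, lgg-1 at -2.36 ± 0.14 and atg-16.2 at -2.1 ± 0.10. Sperm genes had positive values in 36 of 37 cases, as many adjusted over the list alone (median 3.51, adjusted p = 2.01e-09, adjusted p = 0.753 with an estimated correlation). Ribosomal protein genes had positive values in 75 of 77 cases, as many adjusted over the list alone (median 0.63, adjusted p = 1.82e-24, adjusted p = 0.654 with an estimated correlation). Of the genes called for loss of daf-1 with hlh-30 intact, 1977 were called in the same direction without hlh-30, where independence would give 995 higher and 846 lower, and 1548 in the opposite direction (r = 0 across genes).

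Of the 34 lists, 3 passed in none of the 16 comparisons: dafachronic acid synthesis and receptor, epidermis markers, and the somatic gonad, vulva and sex-determination genes. Between hlh-30 mutants and N2 in ARD the first gave 1 higher and 4 lower of 11 genes (adjusted p = 0.509), the second 5 and 3 of 15 (0.721) and the third 2 and 2 of 16 (0.729). P-values per gene measure spread between samples as labelled, and camera p-values compare lists to other genes.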

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

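The breakdown of regroupings by how evenly they exchange libraries was chosen only after the result was seen. The log2 change on refeeding differed between hlh-30 mutants and N2 for 4627 genes by the interaction test. Of 100 regroupings that exchange libraries between the 2 groups of each pair, 5 gave as many, the real one included (highest other 8086), so that count does not exclude chance. The others with as many genes were uneven, exchanging more libraries in 1 pair than in the other, which points to the structure of the samples. Among 84 even exchanges the highest count was 139. The genes were chil-28 (6.81), cyp-34A9 (5.75), fbxa-164 (5.57), cpr-2 (5.23), lon-1 (-4.32), scl-6 (-4.26), mltn-9 (-3.99) and vit-1 (-3.95). DAF-16 and insulin-signalling responsive genes (median 1.32) and gluconeogenesis, glyoxylate and trehalose genes (median 0.36) differed as lists.

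Between the double mutant and hlh-30 mutants the refeeding response differed for 6345 genes. Of 100 regroupings 2 gave as many: the real one and an uneven exchange (6540), which does not test chance alone. The highest of 91 even exchanges was 3349. The genes were lips-14 (5.40), cdc-25.3 (4.24), rgs-9 (3.93), col-135 (3.54), col-2 (-6.13), grl-20 (-5.81), grl-21 (-5.76) and col-85 (-5.42).

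The effect of losing daf-1 differed between worms without and with hlh-30 for 6565 genes in ARD, where 2 of 100 regroupings gave as many (highest other 8246, highest of 83 even exchanges 3138), and for 10033 genes after refeeding, where 1 of 100 did (highest other 7145, highest of 87 even exchanges 5731). The other in ARD was uneven. In ARD the genes were lipl-3 (5.67), acdh-1 (4.63), lys-6 (4.42), pmp-5 (4.39), skr-7 (-6.33), sea-1 (-6.03), srw-85 (-5.88) and dpy-14 (-5.86). After refeeding they were col-88 (11.42), col-161 (9.30), col-133 (9.09), col-162 (8.16), col-74 (-8.41), sri-36 (-8.32), col-165 (-8.31) and skr-8 (-8.09), and the autophagy list (median -1.01) differed too. Of these, col-88, col-161 and col-162 were already far lower in refed hlh-30 mutants than in N2.

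In 8 of 96 tests, which share libraries, 1 of a group's 4 libraries lay far from the others. Chance gives about 1 in 20. In normalized counts, parg-2 was at 647 in the refed double mutant replicate 1 (others 91.9 to 118), and mtl-1 at 152.2 in the same library (others 30.7 to 36.8). The gene mtl-1 was at 36.8 in refed daf-1 mutants replicate 3 (others 67.8 to 72), and fmo-2 at 15.9 in the refed double mutant replicate 2 (others 5.11 to 6.56). In N2 in ARD, chil-28 was at 603 in replicate 2 (others 2900 to 3230) and tbb-6 at 46.9 in replicate 3 (others 68 to 71.8). The gene spp-17 was at 19.4 in hlh-30 mutants in ARD replicate 4 (others 8.49 to 9.45), and col-2 at 21.5 in refed N2 replicate 3 (others 1.1 to 1.89).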

How the results depend on the processing

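Library weights and leaving out the 3 libraries farthest from their group mean were chosen only after the data were seen. Changing the pseudocount to 0.5 or 5, dropping the filter and adding a replicate block (8140 genes between hlh-30 mutants and N2 in ARD, as without it) left every count of genes within 1.5 times its value. The replicate block ended the call of C-type lectins on refeeding of the double mutant (median -0.28, adjusted p = 0.0522), and a block by batch tag ended it too (0.0512) and that of germ cells and meiosis between daf-1 mutants and N2 in ARD (median -0.04, adjusted p = 0.069); the blocks changed no other call. Tests for counts were planned and not run, since whole reads were not recovered. Library weights raised the number of genes to 12463 and 11333 for hlh-30 mutants against N2 in ARD and refed, 10098 for the double mutant against hlh-30 mutants refed, 9249 for it against N2 refed (with 16 lists), 7595 for daf-1 mutants against N2 in ARD, 9384 for refeeding of hlh-30 mutants, 8670 for its difference from N2, 10259 for the difference in the effect of daf-1 in ARD and 6279 for the genes moved back after refeeding; the cause was not tested. A fit of the compared groups alone has fewer libraries and gave 5221 genes for the double mutant against N2 in ARD, 677 for daf-1 mutants against N2 in ARD and 8537 for refeeding of hlh-30 mutants; 4841 genes differed between daf-1 mutants and N2 in ARD without the 3 far libraries. For that comparison leaving out 1 library gave 1569 (daf-1 replicate 4), 1715 (daf-1 replicate 2) to 3387 (N2 replicate 1). With quantile normalization 2496 genes had a positive and 3310 a negative difference in the effect of daf-1 in ARD.

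With an estimated correlation the lists that passed went, in the order of the comparisons in the report, from 8, 8, 21, 12, 17, 10, 18, 12, 15, 16, 18, 24, 16, 24, 23 and 15 to 2, 0, 2, 0, 0, 0, 0, 0, 1, 2, 0, 0, 2, 0, 0 and 1, since the lists' genes vary together. Quantile normalization left 9 lists for the difference between hlh-30 mutants and N2 in refeeding, and turned 3: ribosomal proteins in the double mutant against hlh-30 mutants refed (-0.08), ribosome biogenesis on refeeding of daf-1 mutants (test direction, median 0.13) and V-ATPase in the difference between hlh-30 mutants and N2 in refeeding (test direction, median -0.01). It ended 24 calls besides 3 turned, library weights 15, leaving out the far libraries 17, and leaving out single libraries 60 of 2530 tried. The daf-1 gene, at -0.02 between daf-1 mutants and N2 in ARD and not past the threshold, was at 0.09 without daf-1 in ARD replicate 2 and 0.01 without N2 in ARD replicate 1. Whether depth or a filter set the table's lowest mean of 1.82 is not given in the sources used here.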

Other observations

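The gene families below, the tests of a variant carried into the double mutant and of chromosomes, and both tests of the low count for daf-1 mutants in ARD were chosen only after the results were seen. Families sharing a name were tested with camera, 118 with at least 10 members tested (second p with an estimated correlation). The pals family, known from responses to intracellular pathogens, had 23 of 33 members higher and 3 lower in hlh-30 mutants than in N2 in ARD (median log2 change 1.56, adjusted p = 0.00203 and 0.995), and 26 higher after refeeding (median 1.43, adjusted p = 1.14e-11 and 0.399). Its median was also up in the double mutant (2.17 in ARD, 1.89 refed) and daf-1 mutants in ARD (0.78). The F-box family fbxa had 98 of 181 members higher and 11 lower in refed hlh-30 mutants (median 0.82, adjusted p = 1.9e-15 and 0.207). In daf-1 mutants in ARD, 16 of 17 members of the nematode-specific peptide family nspc were lower than in N2 (median -1.59, adjusted p = 6.06e-35 and 0.00962). The transthyretin-related family ttr had 35 of 58 members higher and 5 lower in the refed double mutant than in N2 (median 0.78, adjusted p = 3.73e-18 and 0.0368), with 0.74 in refed hlh-30 and 0.49 in refed daf-1 mutants.

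On refeeding of N2, 26 of 27 genes of the flp family of neuropeptides fell (median -1.11, adjusted p = 2.07e-10, 0.699 with an estimated correlation), and 24 had a positive interaction in hlh-30 mutants (median 0.83, adjusted p = 4.51e-10, 0.581 with an estimated correlation).

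In hlh-30 mutants 81 genes were more than 16-fold higher than in N2 in both conditions, with median log2 changes of 5.26 in ARD and 5.79 after refeeding. The groups overlap for 0% of them, which their choice largely fixed, so a single library was not tested. Of these genes 1.2% lie within 2 Mb of hlh-30 against 3.7% of all genes tested (Fisher's exact p = 0.375), which speaks only of effects on neighbouring genes, and 45 lie on chromosome V (55.6% against 21.4%, Fisher's exact adjusted p = 1.13e-10 over 6 chromosomes); a variant there was not told apart from gene families that lie together. A variant linked to the deletion or elsewhere in the strain that acts on distant genes remains a candidate explanation if carried into the double mutant: the ratio of the medians of the double mutant to those of hlh-30 mutants was 0.48 in ARD (0.45 to 0.50 with 1 library left out) and 0.23 after refeeding (0.19 to 0.25), and the value in ARD does not clear its bound. The loss of hlh-30 itself stays open too, and no rescued strain was analysed here.

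Collagen genes were higher in the double mutant than in hlh-30 mutants in ARD, with a median log2 change of 2.43. It was 2.12 without the double mutant in ARD replicate 1 and 2.47 with quantile normalization, which argues against that library or the authors' scaling as its cause. Over the 30 libraries, deviations from group means of the 162 collagen genes followed those of the 35 molting cycle genes (Pearson r = 0.96, permutation p = 1e-05, the smallest that 100000 resamples can give; Spearman rho = 0.85, permutation p = 5e-05; r = 0.92 without the 2 libraries farthest out). With group means removed, this r does not test the difference between groups. The stage of the molt and a direct effect of daf-1 or hlh-30 stay open and were not tested.

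Fewer genes were called between daf-1 mutants and N2 in ARD (2743) than after refeeding (11643). With 1 refed daf-1 library left out the refed count stayed at 11049 or more, which argues against the smaller group as the whole cause. Spread between libraries stays open: the count in ARD was 3266 without N2 in ARD replicate 2, 4841 without the 3 far libraries and 7595 with library weights (12988 refed). A difference in the action of daf-1 between the conditions was not tested as such.

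In all 12 comparisons only the real split of the libraries of 2 groups gave as many genes (1 of 35, the fewest possible). Between hlh-30 mutants and N2 the counts were 8140 in ARD and 7134 refed (highest others 1951 and 4711). For the double mutant they were 10248 and 5720 against hlh-30 mutants (highest others 867 and 4734), and 9559 and 6158 against N2 (6968 and 2221). Between daf-1 mutants and N2 they were 2743 and 11643 (2665 and 160). Chance stays open in ARD there (1569 to 3387 with 1 library left out). For refeeding of N2, hlh-30, daf-1 and double mutants the counts were 9725, 4732, 11409 and 12750 (4859, 2484, 9198 and 10911). Among the 8 splits of each comparison that part as many libraries of the same number, the highest others were 1951, 4422, 867, 3323, 0, 1, 525, 0, 1639, 2484, 6638 and 1 in the same order; the remaining splits keep at least 1 such pair together.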
